A study of Nematostella vectensis with 4 samples.

How the data were processed

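Single-cell RNA was measured in 4 libraries of sub-adult Nematostella vectensis polyps aged 5 months, 1 library each from tentacle, mesentery, pharynx and body wall. Per the labels' protocols, the dissected tissues were dissociated with a trypsin-like enzyme and loaded on the Chromium controller of 10x Genomics with version 2 reagents. The sources used here do not say how many animals were pooled, and nothing in them marks any library as a replicate of another. The deposited matrices hold whole-number UMI counts per gene model and barcode, which the authors made with Cell Ranger 2.1.0 per the submitters' processing notes. The genome build and the settings of alignment and barcode calling are not given in the sources used here. Each matrix has 25734 gene rows and 7000 barcodes, with no normalization applied.

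Of the gene rows, 17269 carry a name beside the model identifier (NVE number) and 8465 do not. Of the names, 16928 end in a species code, that is, they are entry names of a protein of another or the same species, and how they were assigned is not given in the sources used here. Since 2530 names were used by more than 1 row (7678 rows in all), each gene is printed with its identifier. None of the identifiers was found in the reference gene table at hand (0 matches), so no gene could be given a position. A name is used here as a pointer to a protein family, and the function of the sea anemone gene was not tested.

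The choices that follow were made before the data were examined, except where stated. Barcodes with at least 300 UMIs were kept (1299 tentacle, 1357 mesentery, 2804 pharynx and 1652 body wall, 7112 in all). Their UMIs were summed per gene and tissue and divided by the tissue's sum, giving UMIs per 1000000 (CPM). With 1 library per tissue there is no replicate error, so no test of a difference between tissues was run and no p-value is given. Ratios carry exact 95% intervals of a Poisson ratio, CPM values exact Poisson intervals and shares exact Clopper-Pearson intervals, all for counting error only. A tissue with 0 UMIs was set to a floor of 3 UMIs per library, and ratios against it are given as bounds. A share of 0 cells is given with the share that 3 cells would make, not with the limit of its interval.

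A gene was called tissue-high when it had at least 50 UMIs in a tissue and a CPM at least 4 times that of each of the other 3 tissues. It was called tissue-low when it had at least 50 UMIs in each of the other 3 tissues and a CPM at most 0.25 times each of theirs. Named for each tissue were the 8 tissue-high genes with a name that had the largest ratio to the second highest tissue, the 4 with the largest UMI sum, and the 3 tissue-low genes with the smallest ratio, plus up to 2 unnamed models. Also named were the 4 most abundant members of each fixed gene list and, within a cell class, the 4 named genes with the largest ratio each way among those with at least 30 UMIs in the higher tissue. Of the leading genes of clusters only a few are printed.

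The 14 gene lists were cnidocyte, neuron, digestive gland, mucus gland, muscle, gastrodermis and nutrient store, epidermis, cycling or germline, immune, dissociation stress, ribosome, mitochondrial genome, extracellular matrix, and cilia. Members were matched on the names in the gene table, with search patterns written after the names were seen. Of the 10 cnidocyte families only 2 matched (4 genes), of the 6 mucus families 3 (23 genes), of the 12 digestive gland families 11 (131 genes), of the 15 muscle families 13 (67 genes), of the 11 gastrodermis families 10 (37 genes) and of the 6 extracellular matrix families 5 (56 genes). The other lists matched in every family, but the mitochondrial genome list was counted as 1 family and matched only 5 genes. For lists with enough genes, the median log2 ratio of a tissue to the mean of the other 3 (10 CPM added) was ranked among 10000 random lists of the same size, matched on expression in 20 bins. Only members with at least 50 UMIs over the 4 tissues entered these medians and percentiles. Such members numbered 40 of 67 for muscle, 60 of 131 for the digestive gland, 60 of 328 for neuron and 26 of 179 for cycling or germline.

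Cells of the 4 libraries were clustered jointly. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were ranked within libraries and combined, and 30 principal components, 15 neighbours and Leiden resolution 1 with seed 1 gave 28 clusters. A cluster's leading genes had the largest ratio of CPM to all other cells (10 CPM added) among genes detected in at least 20% of its cells. A cluster was named after a list when at least 3 list members of at least 2 families stood among its 30 leading genes. The further demand of at least 2 members among the first 10 was set after seeing the data, and it left clusters 8, 10 and 12 unnamed. Clusters 20 and 26 had at least 3 markers but of 1 family, so they were left unnamed by the first rule. The sets of clusters with at least 5000 CPM of Ncol3 and with cilia markers were also set after seeing the data. Within-class comparisons needed at least 50 cells in both tissues. Shares of cells with a UMI were taken after thinning each cell to 300 UMIs, and the similarity of tissues is Pearson's r across genes of log2(CPM + 10) with a bootstrap interval over genes (1000 draws).

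The procedure was tested on simulated data with known changes, drawn as Poisson UMI sums per tissue from a pooled profile. These data hold no variation between cells or libraries. They check the working of the rules, and not the rate of false calls in real libraries. All of 67 genes raised 8-fold and all of 67 raised 16-fold in the tentacle were called tissue-high, 0 of 66 raised 2-fold were called, and 0 of 25534 unchanged genes were called. The 95% ratio intervals held the true ratio for 96.2% of 500 genes. In a list test, a raised list of 67 genes reached percentile 100 and an unchanged list of 40 genes percentile 79.5.

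Alternatives tried were minimums of 200 and 500 UMIs per barcode and no minimum, a gene minimum of 20 UMIs and none (where the demand for more UMIs than the floor was set after seeing the data), median-of-ratios size factors and TMM factors, equal weight per cell, removal of Scrublet doublets and of barcode sequences kept in more than 1 library (7 tentacle, 11 mesentery, 15 pharynx and 11 body wall), Leiden resolutions 0.5 and 2, clustering without tissue-high genes, on each library alone and after thinning, lists without their most abundant gene, log2(CPM + 1), and thinning to 500 UMIs or none. Relative to CPM, size factors moved the body wall by 0.11 and TMM factors by 0.12 on the log2 scale, and the other 3 tissues by less than 0.1. Scrublet's own threshold marked 15 of the 7112 kept barcodes (0.211%), too few to have worked, so removal of the 5% highest scores per library (356 barcodes) was added after seeing the data. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.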

Results

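Transcripts of single cells were counted in 4 tissues of the starlet sea anemone Nematostella vectensis at 5 months of age: the tentacles, the mesenteries (the internal folds of the gut cavity), the pharynx and the body wall. There was 1 library per tissue, so no value has a replicate error, and all intervals (95%) cover counting error only. The libraries held 2637057 UMIs (tentacle), 2517855 (mesentery), 3499510 (pharynx) and 2817054 (body wall) over 7000 barcodes each. Barcodes with at least 300 UMIs numbered 1299, 1357, 2804 and 1652 in the same order, with medians of 703, 542, 563 and 766 UMIs. A count of 3 UMIs, the floor used for a tissue with none, equals 1.63, 1.92, 1.09 and 1.50 UMIs per 1000000 UMIs of the tissue (CPM). The rows for the reporters eGFP, memCerulean, mCherry and memOrange2 held 0 UMIs in all barcodes of the 4 libraries.

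The first comparison asked which genes set each tissue apart from the other 3. The tentacle had the most tissue-high genes, 348 (195 of them named), followed by the body wall with 226 (121 named), the mesentery with 148 (87 named) and the pharynx with 134 (71 named). These genes took 17.8% of the tentacle's UMIs, 7.34% of the body wall's, 4.88% of the mesentery's and 1.94% of the pharynx's. Tissue-low genes were fewer, with 64 in the tentacle, 34 in the body wall, 20 in the mesentery and 6 in the pharynx. Of the tissue-high genes, 19 in the tentacle, 32 in the mesentery, 19 in the pharynx and 24 in the body wall had 0 UMIs in the other 3 tissues.

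In the tentacle, Ncol3 (NVE9976), a minicollagen of the wall of the stinging capsule, was the named tissue-high gene with the most UMIs, at 9755 CPM (9613 to 9898), 6.39-fold above the pharynx (6.18 to 6.61). Genes named after calcium-binding proteins of the secretory pathway, CALU_HUMAN (NVE221) and RCN1_HUMAN (NVE4164), had 1137 and 1046 UMIs in the tentacle and 0 in the other 3 tissues, at least 321-fold and at least 296-fold above the mesentery. XYLT_DROME (NVE15705), named after a xylosyltransferase that starts proteoglycan sugar chains, stood at 823 CPM, at least 429-fold above the mesentery. Genes named after the extracellular proteins brevican (PGCB_HUMAN, NVE17236, and PGCB_BOVIN, NVE2179) and matrilin (MATN4_MOUSE, NVE253) stood at 469, 739 and 472 CPM. PGCB_HUMAN was at least 245-fold above the mesentery, PGCB_BOVIN 136-fold above the pharynx (82.0 to 243) and MATN4_MOUSE at least 315-fold above the body wall. T194A_PONAB (NVE18972) had 11028 UMIs, 283-fold above the mesentery (202 to 412), and MFGM_RAT (NVE13087) was at least 166-fold above the mesentery. EVA1C_PANTR (NVE3845) at 5056 CPM and CSL3_ONCKE (NVE7724), named after a rhamnose-binding lectin, at 4966 CPM were 6.79-fold and 8.60-fold above the pharynx. The unnamed models NVE18957 and NVE18950 had 16274 and 5057 UMIs in the tentacle against 0 in the body wall. IELA_ANESU (NVE23807), GPR98_DANRE (NVE21119) and CP3A4_HUMAN (NVE11461), named after a cytochrome P450, were lowest in the tentacle, with 2, 1 and 1 UMIs and ratios to the pharynx of 0.0173 (0.00208 to 0.0634), 0.0220 (0.000549 to 0.127) and 0.0230 (0.000573 to 0.133).

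In the mesentery, the named genes with the largest ratios included genes named after proteases. HE_PARLI (NVE21084), named after a hatching enzyme, stood at 1117 CPM, at least 687-fold above the tentacle. NAS13_CAEEL (NVE25752), named after an astacin metalloprotease, stood at 295 CPM, 163-fold above the pharynx (69.3 to 504). PLMN_MOUSE (NVE21873) and CTRB_BOVIN (NVE4653), named after the serine proteases plasminogen and chymotrypsinogen, were at least 572-fold and at least 266-fold above the tentacle. A pair of models named CPP1_ACRMI, NVE16289 and NVE4604, had 1481 and 641 UMIs, against 10 and 3 in the pharynx. TYR3_CAEEL (NVE11693), named after a tyrosinase, and CRA1B_DANRE (NVE20024) had 632 and 430 UMIs and 0 in the other 3 tissues. The most abundant named mesentery-high genes were 3 models named after the phospholipase A2 of a sea anemone, PA2_URTCR (NVE18269, NVE18268 and NVE10958). They stood at 7418, 5509.9 and 3151 CPM, 4.92-fold (4.75 to 5.10), 5.26-fold (5.04 to 5.49) and 4.83-fold (4.57 to 5.10) above the pharynx. GAPR1_HUMAN (NVE18451) stood at 2221 CPM, 9.76-fold above the pharynx (8.96 to 10.6). Unnamed NVE23274 and NVE5855 had 1594 and 1438 UMIs in the mesentery and 0 in the tentacle. CSL3_ONCKE (NVE7724) had 0 UMIs in the mesentery, at least 84.3-fold lower than in the body wall, and GP2_CANFA (NVE20813) and MOXD1_MOUSE (NVE7358) had 1 UMI each, with ratios to the pharynx of 0.0223 (0.000558 to 0.128) and 0.0271 (0.000676 to 0.156).

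In the pharynx, with 0 UMIs set to the floor of 3, the largest ratio of a named gene belonged to COCA1_MOUSE (NVE1555), named after collagen XII. It stood at 424 CPM and 221-fold above the mesentery (75.4 to 1073, on 3 mesentery UMIs), and genes given as bounds may exceed it. CPP1_ACRMI (NVE1213) followed at 583 CPM, 182-fold above the mesentery (78.0 to 563). Genes named after hatching enzymes, HE_HEMPU (NVE23939) and HE_PARLI (NVE23940), were at least 158-fold and at least 67.5-fold above the mesentery, and differ from the HE_PARLI model of the mesentery. FBLN1_DANRE (NVE4720), named after the matrix protein fibulin, and AGUA_PSEA8 (NVE20608) were at least 50-fold above the tentacle and at least 26.1-fold above the mesentery. SAP3_MACFA (NVE13048) was 28.8-fold above the mesentery (9.65 to 141), and NvMoxD (NVE10742), a homeobox gene, 22.0-fold above the tentacle (9.91 to 60.6). HMCN1_HUMAN (NVE10021), named after the matrix protein hemicentin, had the most UMIs of the named pharynx-high genes, 3153. It was 7.07-fold above the mesentery (6.22 to 8.07), with 0 UMIs in the tentacle and body wall. Unnamed NVE26012 and NVE5004 had 4904 and 2348 UMIs in the pharynx and 0 in the other 3 tissues. YTCJ_BACSU (NVE19696) was 9.45-fold lower in the pharynx than in the body wall, and FAXC_XENTR (NVE8298) and MAFG_CHICK (NVE3871), named after a small Maf transcription factor, were 5.81-fold and 5.46-fold lower than in the mesentery.

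In the body wall, CO7A1_MOUSE (NVE21527), named after collagen VII, and CHIT_BRUMA (NVE9103), named after a chitinase, had 4882 and 4240 UMIs, at least 1269.9-fold and at least 1103-fold above the mesentery. A trio of models with names of Nematostella toxins, TX371_NEMVE (NVE1809), TX411_NEMVE (NVE1812) and TX451_NEMVE (NVE1813), had 2717, 2574 and 995 UMIs in the body wall and 0 in the other 3 tissues, at least 707-fold, at least 670-fold and at least 259-fold above the mesentery. HMCN2_HUMAN (NVE6997), named after a hemicentin, and COCA1_CHICK (NVE13799), named after collagen XII, were at least 334-fold and at least 281-fold above the mesentery. GXN_ACRMI (NVE4779), named after the coral matrix protein galaxin, stood at 579 CPM and 798-fold above the pharynx (220 to 6593, on 2 pharynx UMIs). Unnamed NVE16219 and NVE1302 had 5390 and 10825 UMIs in the body wall against 0 and 7 in the mesentery. A pair of myosin light chain models, MYL9_MOUSE (NVE20160) and MLC2_DROME (NVE3912), had 0 UMIs in the body wall and were there at least 576-fold and at least 487-fold lower than in the pharynx. PA2_URTCR (NVE18269) also had 0 UMIs there, at least 228-fold lower than in the tentacle. Of the tissue-high genes, 262 in the tentacle (75.3%), 122 in the mesentery (82.4%), 81 in the pharynx (60.4%) and 166 in the body wall (73.5%) stayed tissue-high under all 11 alternatives.

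**Figure D1:**
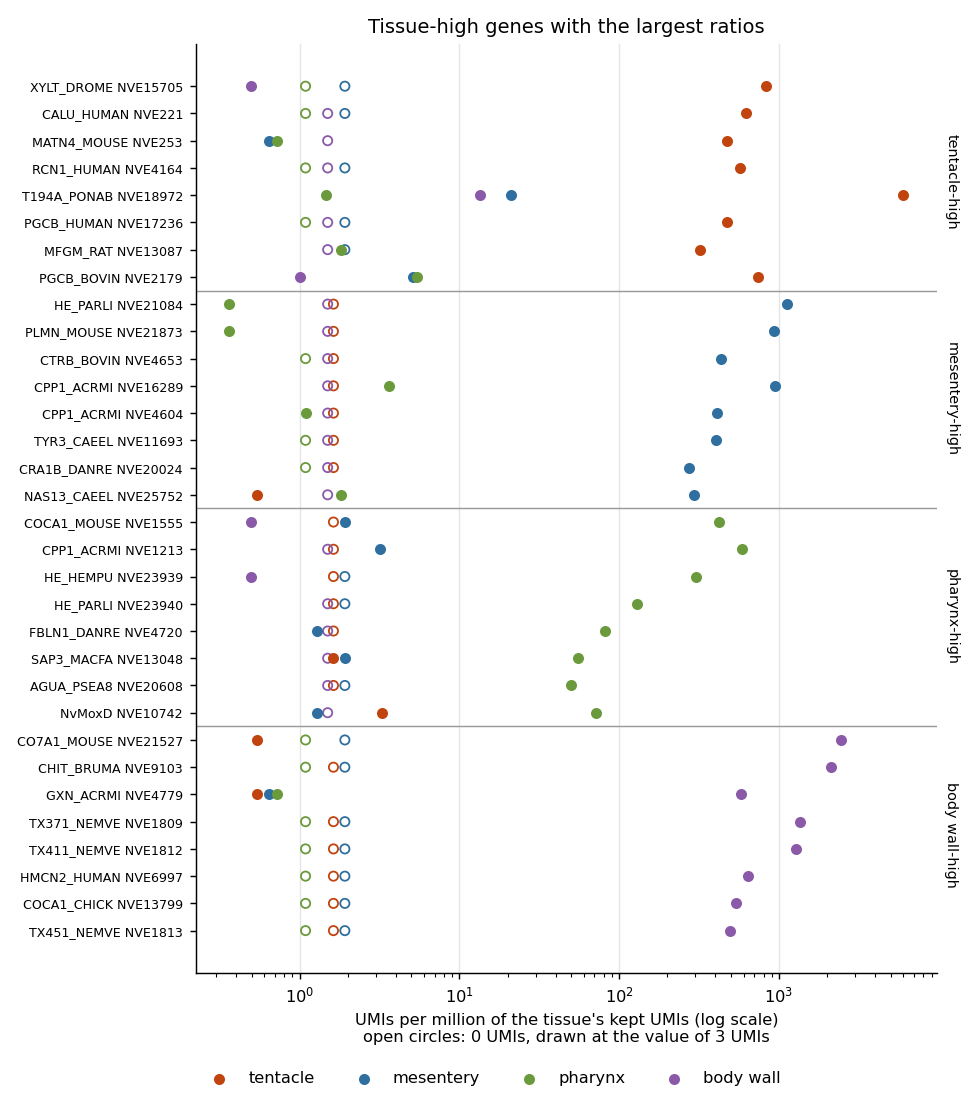
CPM (log scale) of the 8 named genes with the largest ratio in each tissue, 1 point per tissue, with open circles for 0 UMIs drawn at the value of 3 UMIs. CO7A1_MOUSE in the body wall stands at 2436 CPM and T194A_PONAB in the tentacle at 5982 CPM, far to the right of the other tissues' points.

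The fixed gene lists asked which kinds of transcripts filled each tissue. The digestive gland list took 2.63% of UMIs in the mesentery (2.60 to 2.65), 0.479% in the pharynx, 0.335% in the body wall and 0.118% in the tentacle. Of its 115 detected members, 28 were mesentery-high, and its median log2 ratio of 1.43 in the mesentery lay above all of 10000 random lists (-1.37 in the tentacle, -1.04 in the pharynx and -1.35 in the body wall, each at percentile 0). Each ratio is to the mean of the other 3 tissues, so genes raised in the mesentery have lowered ratios elsewhere. The values of a list are therefore not independent of each other. The abundant members were the 3 PA2_URTCR models in the mesentery and CHIT_BRUMA (NVE9103) in the body wall at 2116 CPM. Without PA2_URTCR (NVE18269) the shares were 1.89% in the mesentery, 0.328% in the pharynx, 0.335% in the body wall and 0.0834% in the tentacle. The pharynx's place above the body wall therefore rested on that gene. Removal of all 3 PA2_URTCR models was not tried. The cnidocyte list, of which only Ncol3 and 3 models named after dickkopf-related protein 3 were matched, took 1.04% in the tentacle (1.02 to 1.05), 0.173% in the pharynx, 0.0583% in the mesentery and 0.0355% in the body wall. DKK3_MOUSE (NVE142) stood at 523 CPM in the tentacle against 56.4 in the body wall, DKK3_CHICK (NVE143) at 85.7 against 8.48, and DKK3_CHICK (NVE13825) had 13 UMIs against 0.

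The muscle list took 0.912% of UMIs in the tentacle (0.898 to 0.926), 0.798% in the body wall, 0.674% in the pharynx and 0.664% in the mesentery, but its members went both ways. Body-wall-low members numbered 5 and tentacle-low members 4 of the 60 detected. MYL9_MOUSE (NVE20160) and MLC2_DROME (NVE3912) stood at 2383 and 1110.4 CPM in the tentacle with 0 UMIs in the body wall, whereas MP20_DROME (NVE7520), named after a calponin-like muscle protein, stood at 1608 CPM in the body wall and 93.3 in the tentacle, 17.2-fold apart (14.8 to 20.2). MYS_ARGIR (NVE14552), named after a striated muscle myosin heavy chain, was 3.38-fold higher in the tentacle than in the body wall (3.10 to 3.68). Without MYL9_MOUSE, the highest share of the list moved from the tentacle to the body wall. Over the 40 members with at least 50 UMIs, the median log2 ratio was 0.05 in the tentacle (percentile 87.4 of random lists), -0.42 in the mesentery (percentile 0.71), -0.21 in the pharynx (percentile 9.09) and -0.19 in the body wall (percentile 32.1).

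The extracellular matrix list took 0.242% in the body wall (0.235 to 0.249), against 0.104% in the pharynx, 0.0909% in the mesentery and 0.0339% in the tentacle, and its median log2 ratio of 0.29 in the body wall was at percentile 99.5 of random lists, against -0.85 in the tentacle (percentile 0), -0.15 in the mesentery (percentile 38.5) and 0.05 in the pharynx (percentile 75.6). The fibrillar collagen models CO1A2_CANFA (NVE12857), CO5A1_HUMAN (NVE21105) and CO5A1_RAT (NVE15238) were 11-fold, 16.6-fold and 19.8-fold higher in the body wall than in the tentacle. PGBM_HUMAN (NVE18733), named after the basement membrane protein perlecan, was highest in the mesentery at 310 CPM, with 36.4 CPM in the body wall. The gastrodermis and nutrient list took 3.88% in the body wall, 3.87% in the mesentery, 3.49% in the pharynx and 1.62% in the tentacle. Its median log2 ratios were 0.06 in the body wall (percentile 88.4), 0.17 in the mesentery (percentile 99.4), 0.24 in the pharynx (percentile 98.8) and -1.06 in the tentacle (percentile 0.01). Without the FRIS_LYMST model with the most UMIs the shares were 2.04%, 2.20%, 1.94% and 1.16%. The iron-storage ferritin models FRIS_LYMST (NVE15943 and NVE14362) were 4.05-fold and 4.07-fold higher in the body wall than in the tentacle, whereas a further FRIS_LYMST model (NVE25570) was highest in the tentacle at 7231 CPM. NPC2_PANTR (NVE18456), named after a sterol carrier, was 4.96-fold higher in the mesentery than in the tentacle (4.74 to 5.20).

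The epidermis list took 0.239% in the pharynx, 0.212% in the tentacle, 0.170% in the body wall and 0.122% in the mesentery. The pharynx share rested on HMCN1_HUMAN (NVE10021), without which it was 0.125% against 0.212% in the tentacle, and the median log2 ratio in the pharynx was -0.34, at percentile 0.03 of random lists (-0.24 in the tentacle at percentile 4.88, -0.61 in the mesentery at percentile 0 and -0.17 in the body wall at percentile 41.5). Its members split by tissue: HMCN1_HUMAN (NVE10021) and NvFoxA (NVE20630), a forkhead transcription factor gene, stood at 1144 and 322 CPM in the pharynx, HMCN2_HUMAN (NVE6997) at 641 CPM in the body wall, and HMCN1_HUMAN (NVE1389) at 275 CPM in the mesentery with 0 UMIs in the body wall. The neuron list took 0.251% in the tentacle, 0.195% in the body wall, 0.177% in the pharynx and 0.134% in the mesentery. Median log2 ratios were 0.06 in the tentacle (percentile 86.7), -0.24 in the body wall (percentile 18.9), -0.25 in the pharynx (percentile 0.3) and -0.48 in the mesentery (percentile 0). ACH2_CAEEL (NVE13969), named after an acetylcholine receptor, was 18.7-fold higher in the body wall than in the mesentery (11.8 to 31.3), while VGLU1_RAT (NVE9481), named after a vesicular glutamate transporter, VAMP3_HUMAN (NVE20764) and STX6_PONAB (NVE18515) differed between their highest and lowest tissues by 1.90-fold, 1.14-fold and 1.59-fold. The immune list took 0.0579% in the tentacle, 0.0390% in the mesentery, 0.0243% in the body wall and 0.0211% in the pharynx. For this list the median log2 ratios were 0.29 in the tentacle (percentile 95.3), 0.15 in the mesentery (percentile 96.8), -0.40 in the body wall (percentile 14.3) and -0.82 in the pharynx (percentile 0.03). Among its members CO6_BOVIN (NVE1601), named after complement C6, stood at 176 CPM in the tentacle and 5.08 in the pharynx, and IFIH1_HUMAN (NVE4706), named after a sensor of viral RNA, at 76.5 and 10.2 CPM. CO3_LAMJA (NVE18540) was highest in the pharynx at 59.9 CPM and IRF2_HUMAN (NVE12489) in the mesentery at 62.0 CPM.

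The mucus gland list took 0.0661% in the tentacle, 0.0670% in the mesentery, 0.0814% in the pharynx and 0.0667% in the body wall, and 0.0420%, 0.00755%, 0.00566% and 0.00449% without ZAN_HUMAN (NVE15136). ZAN_HUMAN (NVE15136), named after zonadhesin, was highest in the pharynx at 758 CPM, LEG_HELCR (NVE19041) and MUC5A_HUMAN (NVE16872), named after a lectin and a mucin, in the tentacle at 338 and 55.3 CPM, and LECG_PATPE (NVE8274) had 63 UMIs in the mesentery and 0 in the other 3 tissues. The cycling or germline list took 0.310% in the mesentery, 0.306% in the pharynx, 0.284% in the body wall and 0.254% in the tentacle. In the same order the median log2 ratios were -0.07 (percentile 51.5), -0.08 (percentile 42.3), -0.41 (percentile 2.71) and 0.06 (percentile 80.2). Without H33_XENTR (NVE15668) the shares were 0.158%, 0.120%, 0.0883% and 0.102%. Nvnos2/Nanos2 (NVE16405), a homolog of a germline regulator, stood at 139 CPM in the pharynx and 138 in the mesentery, against 14.6 in the tentacle and 20.5 in the body wall, whereas the histone models H33_XENTR (NVE15668) and H2A_ACRFO (NVE11853) were highest in the body wall at 1956 and 450 CPM and H2A_ACRFO (NVE18284) in the mesentery at 399 CPM.

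The dissociation stress list took 2.64% in the pharynx (2.62 to 2.66), 2.1% in the body wall, 1.63% in the mesentery and 1.53% in the tentacle. The median log2 ratios were, in the same order, 0.11 (percentile 98.8), -0.32 (percentile 5.01), -0.09 (percentile 46.4) and -0.04 (percentile 70.7). Without FOSX_MSVFR (NVE23145) the shares were 1.98%, 1.28%, 1.35% and 1.22%, so the body wall's place above the mesentery rested on that gene. HS71L_BOVIN (NVE15435), named after a heat-shock protein 70, stood at 3645 CPM in the pharynx and 795 in the body wall, 4.59-fold apart (4.35 to 4.84), while FOSX_MSVFR (NVE23145), named after the early response factor Fos, was highest in the body wall at 8190.1 CPM. The model c-jun (NVE21090) and HSP7C_RAT (NVE4209) were highest in the pharynx at 2625 and 1982 CPM. The ribosome list took 29.4% in the tentacle, 34.6% in the mesentery, 31.8% in the pharynx and 34.0% in the body wall. Its median log2 ratios were -0.19 (percentile 53.8), 0.11 (percentile 99.92), -0.06 (percentile 20) and 0.11 (percentile 93.2). RL8_XENTR (NVE23701), RS10_HUMAN (NVE2161), RS8_SPOFR (NVE19312) and RS27A_CHICK (NVE22476) differed between tissues by at most 1.41-fold. The cilia list took 0.594% in the tentacle, 0.482% in the mesentery, 0.495% in the pharynx and 0.467% in the body wall. The median log2 ratio, however, was -0.23 in the tentacle (percentile 12.4), -0.26 in the mesentery (percentile 7.21), 0.05 in the pharynx (percentile 91.8) and -0.85 in the body wall (percentile 0.01). TBA_XENLA (NVE24199) and TBB4_XENLA (NVE5239) differed by at most 1.17-fold, TBB_PARLI (NVE6609) was highest in the mesentery at 870 CPM and TBB_PARLI (NVE25565) in the tentacle at 715 CPM. The mitochondrial list, with only 5 genes matched, took between 0.00559% (tentacle, 103 UMIs) and 0.0113% (body wall, 226 UMIs). These shares do not measure the transcripts of the mitochondrial genome as a whole. COX2_METSE (NVE18805), CYB_METSE (NVE8800), COX1_METSE (NVE2183) and NU2M_METSE (NVE11852) stood at 59.4, 43.9, 5.99 and 2.99 CPM in the body wall. The tissue with the highest share changed under at least 1 alternative for the mucus gland, muscle, gastrodermis, epidermis and cycling lists.

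**Figure D2:**
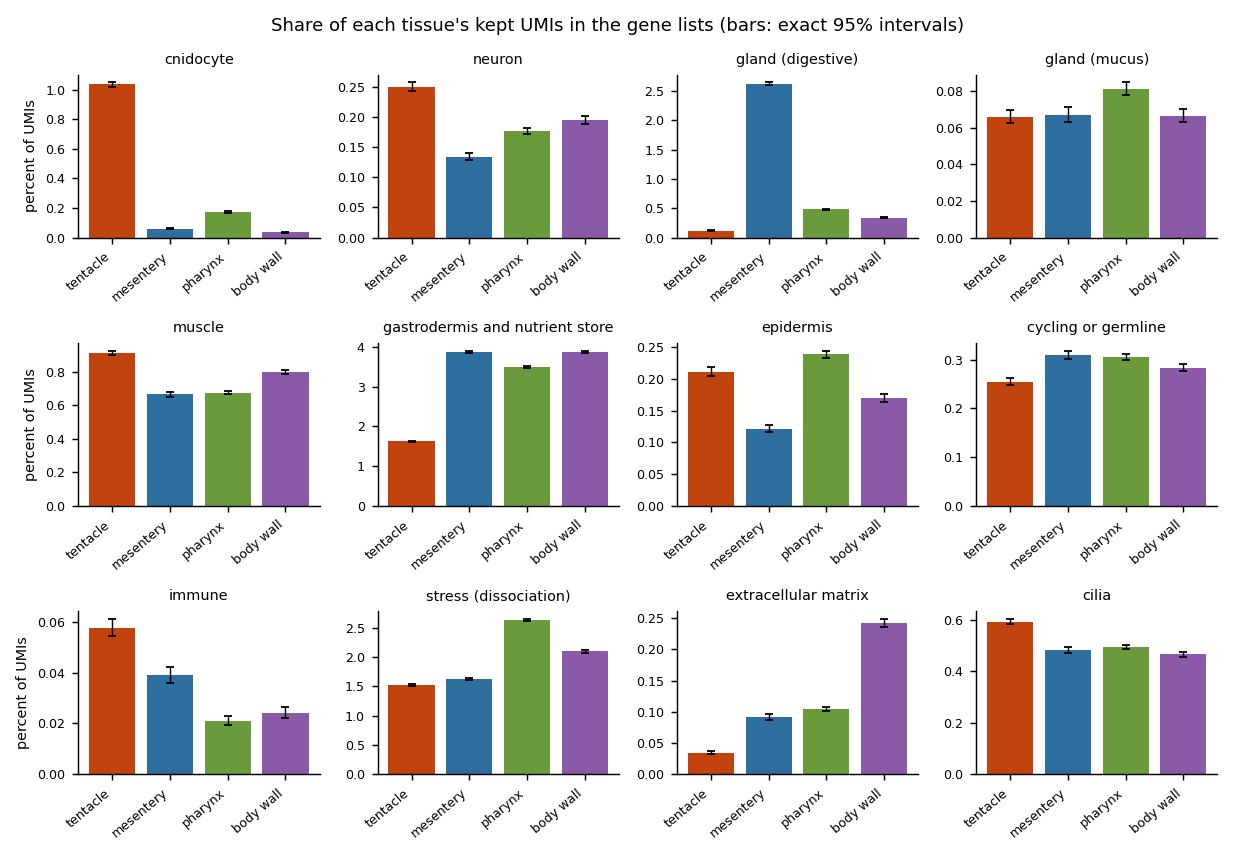
Percent of the tissue's kept UMIs in each gene list except ribosome and mitochondrial genome (1 panel each, axes from 0), by tissue, with exact 95% intervals. The digestive gland list peaks in the mesentery at 2.63% and the cnidocyte list in the tentacle at 1.04%.

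**Figure D3:**
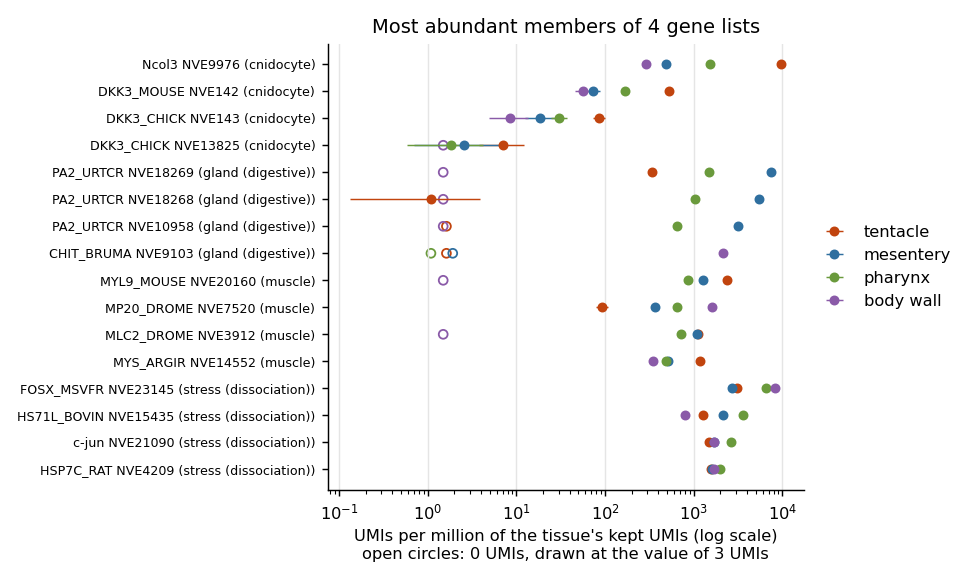
CPM (log scale, exact 95% intervals) of the 4 most abundant members of the cnidocyte, digestive gland, muscle and stress lists, 1 point per tissue, with open circles for 0 UMIs drawn at the value of 3 UMIs. MYL9_MOUSE and MLC2_DROME are at 0 UMIs in the body wall alone.

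The clusters asked how the cell content of the tissues differed. Clusters with Ncol3 above 5000 CPM (11, 15, 22 and 24) held 27.3% of tentacle cells (24.9 to 29.8), 4.35% of pharynx cells (3.63 to 5.17), 1.92% of mesentery cells (1.26 to 2.79) and 1.21% of body-wall cells (0.741 to 1.86). Without the tissue-high genes the shares were 21.2%, 3.71%, 1.62% and 1.03%. These clusters were themselves split by tissue, since cluster 15 was 95.9% tentacle and cluster 22 was 89.5% pharynx. A cluster with cilia markers (12) held 5.53% of pharynx cells (4.71 to 6.44), 2.31% of tentacle, 1.11% of mesentery and 0.0605% of body-wall cells, and 5.67%, 2.54%, 1.33% and 0.0605% without the tissue-high genes. No such cluster was found at 200 UMIs or after thinning (0% in each tissue), and the pharynx share was 3.14% at resolution 2 and 9.02% at 500 UMIs. Cluster 12 also carried heat-shock genes at 3.37% of its UMIs, with 35928 CPM in its pharynx cells and 10229 CPM in its tentacle cells.

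The muscle-like class (clusters 6, 19 and 21) held 15.4% of body-wall cells (13.7 to 17.3), 10.6% of tentacle cells (9.0 to 12.4), 4.96% of pharynx cells and 4.79% of mesentery cells. All 255 body-wall cells of the class lay in cluster 6, while 80 of the 138 tentacle cells lay in cluster 21, and cluster 19 held 40 mesentery and 47 pharynx cells. Without the tissue-high genes only a muscle-like cluster of 194 cells remained, with 7.39% of tentacle, 3.10% of mesentery, 2.00% of pharynx and 0% of body-wall cells, so the ranking of the tissues rests on the naming of cluster 6. The body-wall share was also 0% at 200 UMIs and at resolution 0.5, and 25.1% after thinning. The unnamed clusters 8 and 10 also had 3 muscle markers among their 30 leading genes. Cluster 8 held 244 body-wall cells (14.8%), 7 pharynx, 4 mesentery and 0 tentacle cells, and cluster 10 held 186 tentacle cells (14.3%), 35 pharynx cells and 0 in the mesentery and body wall.

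The digestive gland-like cluster 25 held 3.54% of mesentery cells (2.62 to 4.66), 0.856% of pharynx cells (0.549 to 1.27), 0 of 1299 tentacle cells, which allows up to 0.231%, and 0 of 1652 body-wall cells, which allows up to 0.182%. The cycling or germline-like cluster 27, with a median of 7140.0 UMIs per cell, held 28 mesentery cells (2.06%) and 3 pharynx cells (0.107%). Without the tissue-high genes neither class was named in any tissue (0%), and the mesentery share of the cycling or germline-like class was 1.13% at 200 UMIs, 4.70% at 500 UMIs and 0% after thinning. The gap to the pharynx was narrower at 500 UMIs, where the pharynx had 2.68%, and with each library on its own (1.99% in the mesentery and 1.60% in the pharynx). Cluster 26, with 3 digestive gland markers, held 38 mesentery cells (2.80%), 11 pharynx cells, 1 tentacle cell and 0 body-wall cells, and cluster 20, with 5 epidermis markers, held 43 tentacle (3.31%), 18 mesentery, 35 pharynx and 0 body-wall cells. Of the 28 clusters, 14 drew at least 75% of their cells from 1 library, and 11 of 27 did so without the tissue-high genes. A cluster that is mostly 1 library, such as cluster 4 with 768 of its 773 cells from the body wall, can reflect that library as well as a cell type.

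**Figure D4:**
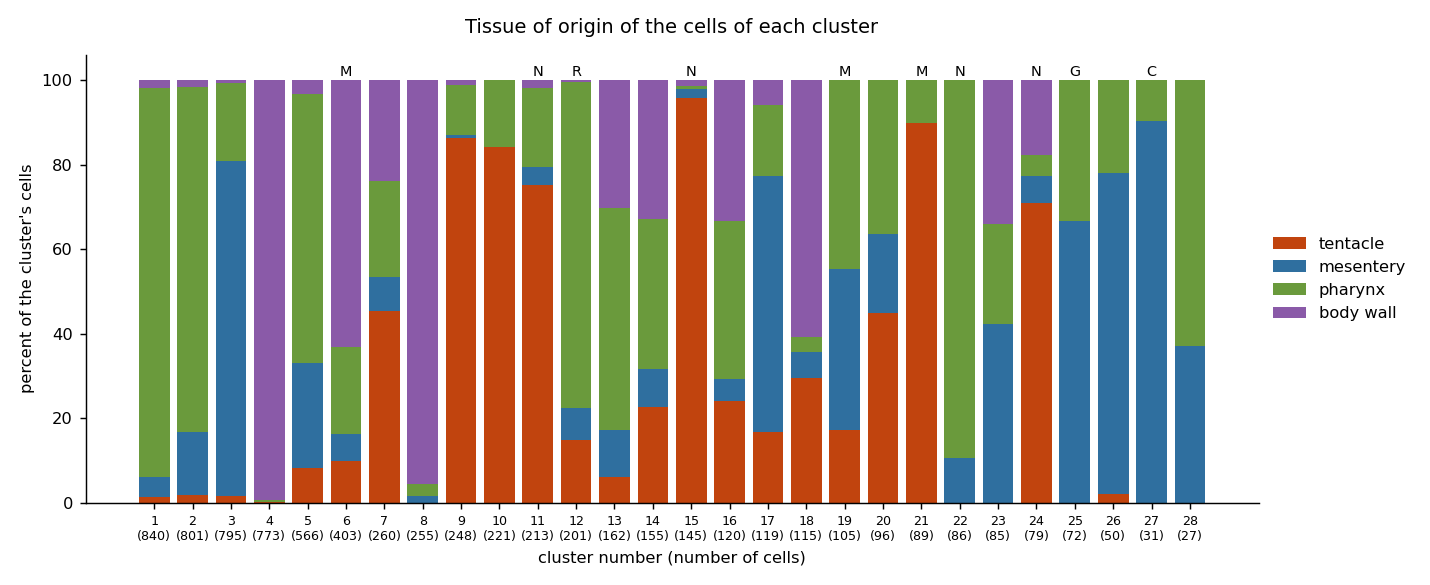
Percent of each cluster's cells by tissue, over the cluster number and its number of cells. Letters mark muscle-like (M), Ncol3-high (N), cilia-marker (R), digestive gland-like (G) and cycling or germline-like (C) clusters, and cluster 4 is 99.4% body wall.

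Within the muscle-like class, the tissues were compared gene by gene, and since all body-wall cells lay in cluster 6, comparisons with the body wall are also comparisons of clusters. Of the 54 gene comparisons that fell under the naming rule, 13 (9 genes) had a CPM in the higher cells under that of the same library's barcodes with fewer than 200 UMIs, and these genes are given with both values. In the tentacle cells MYL9_MOUSE (NVE20160), MLC2_DROME (NVE3912) and TPM4_MOUSE (NVE1725), named after a tropomyosin, stood at 28690.5, 13438.5 and 9724 CPM, against 0 UMIs in the body-wall cells, at least 1685-fold, at least 789-fold and at least 571-fold higher. In the mesentery cells MYL9_MOUSE, MLC2_DROME, TPM4_MOUSE and CSRP1_COTJA (NVE7822), named after a cysteine-rich LIM domain protein, were at least 1390.4-fold, at least 1174-fold, at least 511-fold and at least 735-fold higher than in the body wall. In the pharynx cells MYL9_MOUSE, MLC2_DROME and TPM4_MOUSE were at least 872-fold, at least 684-fold and at least 270.2-fold higher, and ACTB_XENLA (NVE2876), named after actin, was 186-fold higher (144 to 245) there and 358-fold higher in the tentacle (277 to 472). In the body-wall cells MYPH_ECHGR (NVE7522), named after myophilin, and GELS1_LUMTE (NVE19183), named after the actin-severing gelsolin, were 93.8-fold (36.4 to 346) and 82.6-fold (35.1 to 255) higher than in the tentacle, and MLC2_DROME (NVE12983), a second model of that name, 47.8-fold (16.1 to 234). CO5A1_HUMAN (NVE21105) was 102-fold higher there (17.9 to 4042), but its 687 CPM lay under the 852 CPM of body-wall barcodes with fewer than 200 UMIs. Against the mesentery, CALL3_RAT (NVE11431), MYPH_ECHGR, SO4C1_MOUSE (NVE4324) and TPM_ECHMU (NVE26034) were 94.4-fold (26 to 782), 67.7-fold (23.0 to 329), 43.6-fold (7.64 to 1739) and 39.1-fold (6.82 to 1560.1) higher in the body wall.

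Counted at 4-fold, 171 genes were higher in the tentacle than in the body-wall cells of the class and 84 the other way, 30 in the mesentery and 66 the other way, and 35 in the pharynx and 38 the other way. A gene needed 30 UMIs in the higher tissue, which 510 genes had in the tentacle, 268 in the mesentery, 421 in the pharynx and 426 in the body wall. In cluster 6 it was 207 in the pharynx and 426 in the body wall. The 2 directions of a pair thus have unequal bases, here and below. Within cluster 6 alone, 3 genes were higher in the pharynx than in the body wall, among them HEBP2_HUMAN (NVE2673) at 19.5-fold (9.86 to 42.7) and ACTB_XENLA (NVE2876) at 4.40-fold (3.08 to 6.30). Their 1104 and 1447 CPM compare with 1021 and 1655 CPM in pharynx barcodes with fewer than 200 UMIs, so ACTB_XENLA lay under that level. In the body wall their 56.8 and 329 CPM compare with 54.4 and 331 CPM in such barcodes. Both genes thus stood near or under the level of such barcodes in both tissues. Their ratios therefore do not show a difference between the cells of cluster 6 themselves. In that cluster 28 genes were higher in the body wall than in the pharynx, led by MYPH_ECHGR (NVE7522) at 33.3-fold (12.9 to 123) and MFNA_META3 (NVE24906) at 15.5-fold (2.66 to 624). MUSK_RAT (NVE3012), named after a muscle receptor kinase, and the galaxin model NVE2195 followed at 12.8-fold (2.18 to 518) and 11.7-fold (3.92 to 57.7), but their 244 and 669.9 CPM lay under the 351 and 1031 CPM of body-wall barcodes with fewer than 200 UMIs.

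Between the tentacle and the mesentery or pharynx, 117 genes were higher in tentacle than in mesentery cells of the class and 23 the other way, and 76 higher in tentacle than in pharynx cells and 35 the other way. These counts also compare different clusters, since cluster 21 held 80 of the 138 tentacle cells, 0 of the 65 mesentery cells and 9 of the 139 pharynx cells. DCYD1_ORYSJ (NVE2343), OX2R_CANFA (NVE23943), GAP1_SCHPO (NVE23708) and NPFF1_RAT (NVE12084), the latter named after a neuropeptide receptor, were 47.4-fold (18.3 to 175), 36.3-fold (6.29 to 1454), 33.6-fold (5.80 to 1347) and 33.0-fold (5.71 to 1325) higher in the tentacle than in the mesentery. MFNA_METS3 (NVE24899) was at least 116-fold higher in the mesentery and at least 25.6-fold higher in the pharynx than in the tentacle, and MP20_DROME (NVE7493) 46.2-fold (12.1 to 392) and 44.1-fold (11.9 to 369). RGMB_HUMAN (NVE15735) and CSEN_HUMAN (NVE20107) were 47.6-fold (15.9 to 234) and 27.7-fold (9.14 to 137) higher in the tentacle than in the pharynx, and Hl1/HES-1 (NVE8464), named after a Notch target, at least 32.3-fold. RBP_CHICK (NVE5421) was 54.4-fold higher there (9.33 to 2189), but its 345 CPM lay under the 969 CPM of tentacle barcodes with fewer than 200 UMIs. Mesentery and pharynx cells differed least, with 5 genes higher in the mesentery, among them CSRP1_COTJA (NVE7822) at 4.33-fold (3.87 to 4.85), and 23 in the pharynx, among them CALL3_RAT (NVE11431) at 37.6-fold (10.2 to 313). Here too the clusters differed, since cluster 6 held 25 of the 65 mesentery cells and 83 of the 139 pharynx cells. HEBP2_HUMAN (NVE2673) was 24.9-fold higher in the pharynx (6.71 to 208), at 622 CPM against 1021 CPM in pharynx barcodes with fewer than 200 UMIs. PA2_URTCR (NVE18269) was 70.2-fold higher in mesentery than in tentacle muscle-like cells (11.9 to 2845), but its 475 CPM there lay under the 8193 CPM of mesentery barcodes with fewer than 200 UMIs, and so did the 375 CPM of PA2_URTCR (NVE18268) against 5876 CPM. MCPI_MELCP (NVE21151), 16.9-fold higher in the pharynx than in the tentacle (5.48 to 84.4), had 343 CPM against 385 CPM in such pharynx barcodes.

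The similarity of the tissues was measured across 4892 genes, which are not independent replicates. The mesentery and pharynx were the most alike pair, with r = 0.838 (0.819 to 0.855), and the tentacle and mesentery the least, with r = 0.647 (0.615 to 0.677). The pharynx and body wall had r = 0.708, the tentacle and pharynx 0.695, the mesentery and body wall 0.691 and the tentacle and body wall 0.654 (0.625 to 0.681). This last interval overlaps that of the tentacle and mesentery, so which pair is least alike is not settled.

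Shares of cells with a UMI, each cell thinned to 300 UMIs, were taken for a gene of 3 lists. The Ncol3-high clusters were chosen by their Ncol3 level, so a high share of Ncol3 there is fixed in advance, and MYL9_MOUSE was among the genes by which clusters 19 and 21 were named. Ncol3 (NVE9976) was seen in 79.7% of the cells of the Ncol3-high clusters in the tentacle (75.2 to 83.8) and 80.3% in the pharynx (72.2 to 87.0), against 4.35% and 0.719% of the muscle-like cells of these tissues, which should lack it. In the mesentery and body wall it was seen in 53.8% (33.4 to 73.4) and 70% (45.7 to 88.1) of the Ncol3-high cells and in 0 of 65 and 0 of 255 muscle-like cells, which allows up to 4.62% and 1.18%. Median depths before thinning were 1296 and 807.5 UMIs in the Ncol3-high cells and 732.5 and 592 in the muscle-like cells. MYL9_MOUSE (NVE20160) was seen in 71.0% of muscle-like cells in the tentacle (62.7 to 78.4), 60.0% in the mesentery (47.1 to 72.0), 38.1% in the pharynx (30 to 46.7) and 0% in the body wall (0 of 255, which allows up to 1.18%), against 1.97%, 3.85%, 0% and 0% of the Ncol3-high cells. These shares follow the make-up of the class, in which clusters 19 and 21 held 98 of 138, 40 of 65, 56 of 139 and 0 of 255 cells in the same order. Their median depths were 557 UMIs in the mesentery and 475 in the body wall for the muscle-like cells, and 1384.5 and 1520.5 UMIs for the Ncol3-high cells. PA2_URTCR (NVE18269) was seen in 22.9% of digestive gland-like cells of the mesentery (12 to 37.3), at a median of 715 UMIs, and in 11.5% of its Ncol3-high cells (2.45 to 30.2). In mesentery barcodes with fewer than 200 UMIs it stood at 8193 CPM, against 7418 CPM over the kept mesentery barcodes. These values point to a background of this transcript across mesentery barcodes, whose size was not measured. In the pharynx PA2_URTCR was seen in 4.17% of the 24 digestive gland-like cells (0.105 to 21.1) and 4.92% of the 122 Ncol3-high cells (1.83 to 10.4), at medians of 633.5 and 807.5 UMIs.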

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

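Of the tests reported here, those on the number of body-wall cells and on the muscle genes gene by gene were chosen only after the result was seen.

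Barcodes with fewer than 300 UMIs, which were not kept for the comparisons between tissues (those under 200 UMIs served as a reference level within a class), held 793613 UMIs in the tentacle, 954133 in the mesentery, 744167 in the pharynx and 813171 in the body wall, a signal in data outside the main measurement that amounts to 30.1%, 37.9%, 21.3% and 28.9% of each library. Free RNA alone would spread each gene over these barcodes at random, with a variance-to-mean ratio near 1, and the leading genes of the clusters had a median ratio of 1.23 under 200 UMIs, with an interval (1.18 to 1.29) that spans the bound of 1.2 set beforehand, and 1.12 in the body wall. The second test argues against free RNA alone: of the barcodes under 200 UMIs, 10.9% in the tentacle, 9.17% in the mesentery, 16.1% in the pharynx and 5.22% in the body wall, the lowest, were richer in the leading genes of 1 cluster than all but 0.1% of barcodes drawn from the pooled profile. Cells with few UMIs may therefore stand among the barcodes left out, beside free RNA, whose share was not measured. Cells with few transcripts, damaged cells and a tissue difference in cell size stay open.

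The muscle-like clusters 19 and 21, which lead in MYL9_MOUSE (NVE20160), held 98 tentacle cells (7.54%), 40 mesentery cells (2.95%), 56 pharynx cells (2.00%) and 0 of 1652 body-wall cells, which allows up to 0.182%. Too few body-wall cells would not account for this, since at the lowest share of the other tissues 33.0 would be expected. Loss of such cells under the minimum of 300 UMIs was tested in the barcodes left out: the 10 leading genes together stood there at 0.197 times the lowest of the other tissues, between the bounds set beforehand, but 6 of the 10 genes, MYL9_MOUSE and MLC2_DROME (NVE3912) among them, had 0 UMIs there, which argues against loss under the minimum as the whole cause. A tissue difference in muscle types is a candidate explanation as a hypothesis only. Loss of these cells during dissection or dissociation of the body wall leaves the same values if none of their RNA reached the barcodes, and stays open.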

How the results depend on the processing

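No paired analysis was possible because there is 1 library per tissue. The removal of the 5% highest doublet scores was chosen after seeing the data, and within-class counts that involve the mesentery, and cluster 6, had too few cells for a minimum of 500 UMIs and gave no value. No ratio of a named gene changed direction. The order of the tissues changed for the muscle-like class, where the body wall fell to 0% at 200 UMIs, at resolution 0.5 and without the tissue-high genes, and the mesentery stood above the pharynx in all alternatives but the removal of the highest doublet scores. For the cilia-marker set the mesentery stood above the tentacle at 500 UMIs (3.63% and 2.03%) and without the highest doublet scores (2.64% and 2.51%), and the body wall, at 0.605%, above both (0% each) with each library on its own. For the cycling or germline-like class the tentacle stood above the pharynx at 200 UMIs (0.205% and 0.0995%) and at 500 UMIs (3.10% and 2.68%), where the body wall also had cells of the class (0.0377% and 1.87%) and, at 500 UMIs, of the digestive gland-like class (0.281%). Ratios of the named tissue-high genes stayed within their intervals in 380 of 432 values and moved in 52 (32 of them among the 48 values with equal weight per cell), of the tissue-low genes in 104 of 108, of the within-class genes in 162 of 186, list shares in 115 of 280, class shares in 103 of 180, and shares of cells with a UMI in 393 of 840. Except where the alternative itself tests more or fewer genes, cells or barcodes, the cause was not tested. With no gene minimum beyond the floor, tissue-high genes were 586 (tentacle), 318 (mesentery), 225 (pharynx) and 378 (body wall) and tissue-low genes 309, 128, 58 and 282. With a minimum of 20 UMIs, tissue-high genes were 230 (mesentery) and 210 (pharynx) and tissue-low genes 133, 61, 11 and 74. With equal weight per cell, tentacle-low genes were 34, and 15 and 23 genes were higher than in tentacle muscle-like cells in those of the mesentery and pharynx. With all barcodes, mesentery-low genes were 35, and the list shares were 0.803% (cnidocyte, tentacle), 2.69% (digestive gland, mesentery), 0.864% (muscle, tentacle) and 2.76% (stress, pharynx). At 200 UMIs per barcode the class shares were 0% (muscle-like, body wall), 1.13% (cycling or germline-like, mesentery), 20.3% (Ncol3-high, tentacle) and 0% (cilia markers, pharynx), with list shares of 0.984% (cnidocyte), 2.60% (digestive gland) and 2.71% (stress). At 500 UMIs they were 20.3% (muscle-like, body wall), 4.70% (cycling or germline-like), 9.02% (cilia markers) and 5.65% (digestive gland-like, mesentery), 24 genes were higher in body-wall than pharynx muscle-like cells, and list shares were 1.11% (cnidocyte), 2.79% (digestive gland) and 2.53% (stress). Without Scrublet doublets the cilia-marker share was 4.60%, and 5 of the 20 class shares, this one included, left their intervals. At resolution 0.5 the muscle-like share of the body wall was 0%, and at resolution 2 the Ncol3-high and cilia-marker shares were 24.8% and 3.14%. Without the tissue-high genes the shares were 0% (digestive gland-like, mesentery), 0% (muscle-like, body wall), 0% (cycling or germline-like, mesentery) and 21.2% (Ncol3-high, tentacle). With each library on its own, the cycling or germline-like share was 1.99% in the mesentery and 1.60% in the pharynx, and other shares were 2.43% (digestive gland-like), 11.3% (muscle-like), 19.3% (Ncol3-high) and 3.39% (cilia markers). After thinning to 300 UMIs they were 25.1% (muscle-like), 0% (cycling or germline-like), 22.3% (Ncol3-high) and 0% (cilia markers). Without the highest doublet scores, they were 22.4% (muscle-like) and 24.9% (Ncol3-high), and list shares were 1.06% (cnidocyte), 2.73% (digestive gland) and 0.948% (muscle). Without the most abundant gene, list shares were 0.0616% (cnidocyte), 1.89% (digestive gland), 0.674% (muscle) and 1.98% (stress). The r of mesentery and pharynx was 0.864 with genes of 20 UMIs and 0.772 with log2(CPM + 1). Depth limits the rest: at 3 UMIs the floor lies between 1.09 and 1.92 CPM.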

Other observations

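Of the tests reported here, that with clusters made without the stress list was chosen only after the result was seen, and the clusters described were picked from the data.

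Leading genes of some unnamed clusters follow, with no list or test behind a cell type. The first 10 of cluster 16 included DLGP5_MOUSE (NVE7848), CKS1_MOUSE (NVE11822), CENPE_MOUSE (NVE16653) and CENPF_HUMAN (NVE9959), but 0 members of the fixed cycling or germline list, of which 2 stood among its first 30. Cluster 16 held 2.23% of tentacle, 0.442% of mesentery, 1.60% of pharynx and 2.42% of body-wall cells. Cluster 10, mostly tentacle cells, was led by CSL3_ONCKE (NVE7724), CNN2_BOVIN (NVE7521), named after a calponin, and GP2_CANFA (NVE20813), and the first and last of these were among the tissue-low genes of the mesentery. Cluster 8, mostly body-wall cells, was led by USOM7_ACRMI (NVE10146), a galaxin model (NVE2195), MUSK_RAT (NVE3012) and MYPH_ECHGR (NVE7522). Cluster 18, with 70 body-wall, 34 tentacle, 7 mesentery and 4 pharynx cells, was led by DMTA2_DANRE (NVE7106), named after a doublesex-related transcription factor, and the model fez-family (NVE2140). Cluster 26 was led by the PA2_URTCR models NVE18268, NVE10958 and NVE18269, seen in 84%, 84% and 90% of its cells.

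Cluster 2 was led by small heat-shock and HSP70 models, HSP11_CAEEL (NVE10283 and NVE3919) and HS71L_BOVIN (NVE15435), and held 654 pharynx cells (23.3%), 120 mesentery cells (8.84%), 14 tentacle cells and 13 body-wall cells. Heat-shock genes took 1.32% of UMIs in the pharynx, 0.909% in the mesentery, 0.717% in the tentacle and 0.662% in the body wall, and 0.998%, 0.735%, 0.708% and 0.638% without cluster 2. Stress across the whole pharynx library cannot be told apart from a cause in some cells. Of the pairs of a cluster and another tissue, 15.4% (4 of 26) were at least 2 times higher in the pharynx. These pairs left out cluster 2, gathered by heat-shock genes. With clusters made without the stress list, 51.9% (14 of 27) were higher in the pharynx, between the bounds set. Of these 27 pairs, 4 were at least 2 times higher, and the median ratio was 1.11. Both 2-fold counts fell short of the 80% of pairs set beforehand for such stress. They also lay under the lower bound set beforehand, below which the pairs would count against such stress. However, 1 of the new clusters, with 1349 of the 2804 pharynx cells, was still led by heat-shock genes, so these pairs do not decide it. Nor do shallow or degraded barcodes separate by depth, since the ratio of 0.958 between the heat-shock shares of pharynx cells with at least 500 UMIs (3.34%) and under 500 (3.48%) is of cells gathered by these genes. The median of cluster 2, 461 UMIs, was on average 0.732 of the medians of the 4 libraries, each counted the same. Most of its cells came from the pharynx and mesentery, whose medians were 563 and 542 UMIs. Stress across the library and shallow barcodes both stay open, as do a cell population that carries heat-shock transcripts in the intact tissue and a cell type that responds to dissociation more than others.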
